A study of Homo sapiens with 86 samples.

How the data were processed

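The authors deposited 3 tables, for right colon (22871 genes, 57 libraries), left colon (20548 genes, 25 libraries) and colon cancer (23566 genes, 4 libraries), each with raw counts and FPKM per gene. The sample labels name TRIzol extraction and oligo-dT selected Illumina TruSeq libraries, and the submitters' processing notes name Novoalign and hg19. The counting tool, the gene annotation and the strand of the libraries are not given in the sources used here, so genes that overlap or closely resemble another gene are reported as uncertain. All 86 samples were mapped to 8 groups by their titles, tissue labels and the deposited column names, and no column belonged to another sample. One UL library lies in the right colon table. The deposited counts were used for every test. FPKM served to compute the gene length implied by count and FPKM in 19383 genes, whose coefficient of variation over libraries was at most 0.0231% and whose difference between tables was at most 0.0549%.

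The tables hold 24730 Ensembl gene identifiers, of which 20921 have a gene symbol in GENCODE 29 or its synonyms, and 20187 are in all 3 tables. Coordinates are those of the deposited tables (hg19, counted from 1). Genes of chromosome Y, XIST and TSIX (45 identifiers) were left out of every test and table of genes. Every gene of the left and right tables had at least 10 counts in at least 1 library, and no such limit was seen in the cancer table. Counts per library ranged from 8.36 to 63.8 M, with a median of 13.1 M. Group medians were 12.2 (SSAP), 13.1 (AP), 14.3 (UR), 12.4 (CR), 13.1 (HP), 15.5 (UL), 13.6 (CL) and 13.0 M (CA). Within each group of a table no 2 libraries looked like copies of one another (lowest chi-squared per degree of freedom 8.36). Pairs across groups or tables were not compared.

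Counts were tested in R 4.3.3 with edgeR 4.0.16: TMM normalization, filterByExpr (minimum count 10, minimum total 15), robust quasi-likelihood fits and 2-sided F tests with Benjamini-Hochberg adjustment over the genes of a comparison. One fit held SSAP, AP, UR and CR, one held HP, UL and CL, and one held all 86 libraries over the 20150 genes of all 3 tables, for SSAP-CR vs HP-CL, CR vs CL and CA against the mean of CR and CL. Levels are mean ± SD of CPM over the libraries of a group, and fold changes are log2 with the SE of the fit. The alternatives were the size factors of DESeq2 1.42.0, its Wald test, limma 3.58.1 with voom and the starting number of the column names as a random block, other filters, thresholds and sets of libraries, and replicate numbers as blocks. The groups, the 12 comparisons, the tests, the gene lists and most of the alternatives were chosen before the data were examined. Alternatives chosen after seeing the data were the removal of the trend on gene length, all 6 UL libraries in 1 fit, leaving out libraries by low starting number, leaving out 2 SSAP libraries without gastric-type genes, and leaving out the CR library with the highest CYP1A1.

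Gene lists were 15 pathway lists and 17 lists of cell type markers or handling stress, with 341 members, of which 331 were matched. The unmatched were GKN1, GKN2, FCGBP, NEUROG1, HOXB7, MRC1, PECAM1, PRSS2, ALAS2 and LEP. Lists were tested with camera of limma, with the correlation between genes estimated per list from the data and Benjamini-Hochberg adjustment over the lists of a comparison. With the preset correlation of 0.01 in place of the estimate, 93 more list tests passed, so camera values near or above 0.05 depend on that choice. Named genes are the 10 with the highest and the 10 with the lowest fold change in SSAP vs CR, AP vs CR and HP vs CL, and 4 and 4 elsewhere, among genes with an adjusted p under 0.05 and a mean of at least 5 CPM in the higher group. Up to 4 genes per list with the smallest adjusted p were added, and any list member as an example of one that did not pass. Immunoglobulin and T cell receptor segments, HLA genes, small and ribosomal RNA genes and genes without a symbol were left out of the ranked genes. A few genes that the rule names are not reported here.

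Whether replicate numbers pair libraries was checked from the correlation of paired libraries after removing group means. For CR and CL the numbers in the titles and in the column names are the same, and 10 of 10 pairs correlated over 0.1 (lowest 0.18, median 0.46, each the best match of its number). For HP and UL the starting number of the column names gave 5 pairs, and 5 of 5 correlated over 0.1 (lowest 0.10, median 0.25). Their own number was the best match in 40%, and not every UL library had a partner. In SSAP and UR 7 of 9 and in AP and UR 9 of 10 such pairs passed 0.1 (lowest -0.12 and -0.17, median 0.29 and 0.45). Their own number was the best match in 44.4% and 80%. As not every pair passed, these were not taken as paired, although AP and UR matched by number more often than HP and UL. A fit of AP vs UR with the number as a block is given below. The title numbers of other groups did not pair. The number is shared by several libraries of 1 group in SSAP (16 numbers in 21 libraries), HP (8 in 10) and AP (8 in 10), and the voom fit gave correlations within a number of 0.32 (right), 0.20 (left) and 0.35 (all).

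In a self-test, counts were simulated for each comparison with the means, dispersions and library sizes of the real data and no group difference, and genes over 5 CPM were changed by 1.5-fold (67 genes), 2-fold (67) or 4-fold (66) before the same edgeR test. It recovered 59.7%, 97.0% and 98.5% in SSAP vs CR (11 false of 181 calls), 41.8%, 83.6% and 98.5% in AP vs CR (7 of 156), 64.2%, 95.5% and 98.5% in SSAP vs AP (5 of 177), and 68.7%, 97.0% and 95.5% in SSAP vs UR (11 of 185). It recovered 53.7%, 95.5% and 100% in AP vs UR (6 of 172), 62.7%, 82.1% and 100% in UR vs CR (9 of 172), 46.3%, 92.5% and 100% in HP vs CL (11 of 170) and 23.9%, 71.6% and 97.0% in HP vs UL (6 of 134). For UL vs CL the shares were 34.3%, 64.2% and 95.5% (3 of 132), for SSAP-CR vs HP-CL 28.4%, 59.7% and 93.9% (3 of 124), for CR vs CL 47.8%, 91.0% and 98.5% (8 of 166) and for CA 29.9%, 74.6% and 95.5% (7 of 140). In SSAP vs CR, DESeq2 recovered 64.2%, 97.0% and 98.5% (18 of 191) and limma-voom 58.2%, 97.0% and 98.5% (8 of 177). A simulated list of 20 changed genes passed camera (adjusted p = 1.2e-29) and 0 of 31 unchanged lists did. Genes and libraries were simulated independently of one another. Real lists are correlated (0.455 for gastric-type genes in SSAP vs CR), so this does not show how often camera finds or misses such lists.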

Results

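Messenger RNA of human colon was compared between 21 sessile serrated adenomas/polyps (SSAP), 10 adenomatous polyps (AP), 15 libraries of uninvolved right colon (UR) and 10 of control right colon (CR). On the left side, 10 hyperplastic polyps (HP) were compared with 5 libraries of uninvolved left colon (UL) and 10 of control left colon (CL). A sixth UL library was deposited with the right colon, and 4 colon cancers (CA) were deposited on their own. Counts per gene were tested with the edgeR quasi-likelihood test, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The labels do not say that each library came from a separate donor, so the p-values measure the spread between these samples.

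**Figure D1:**
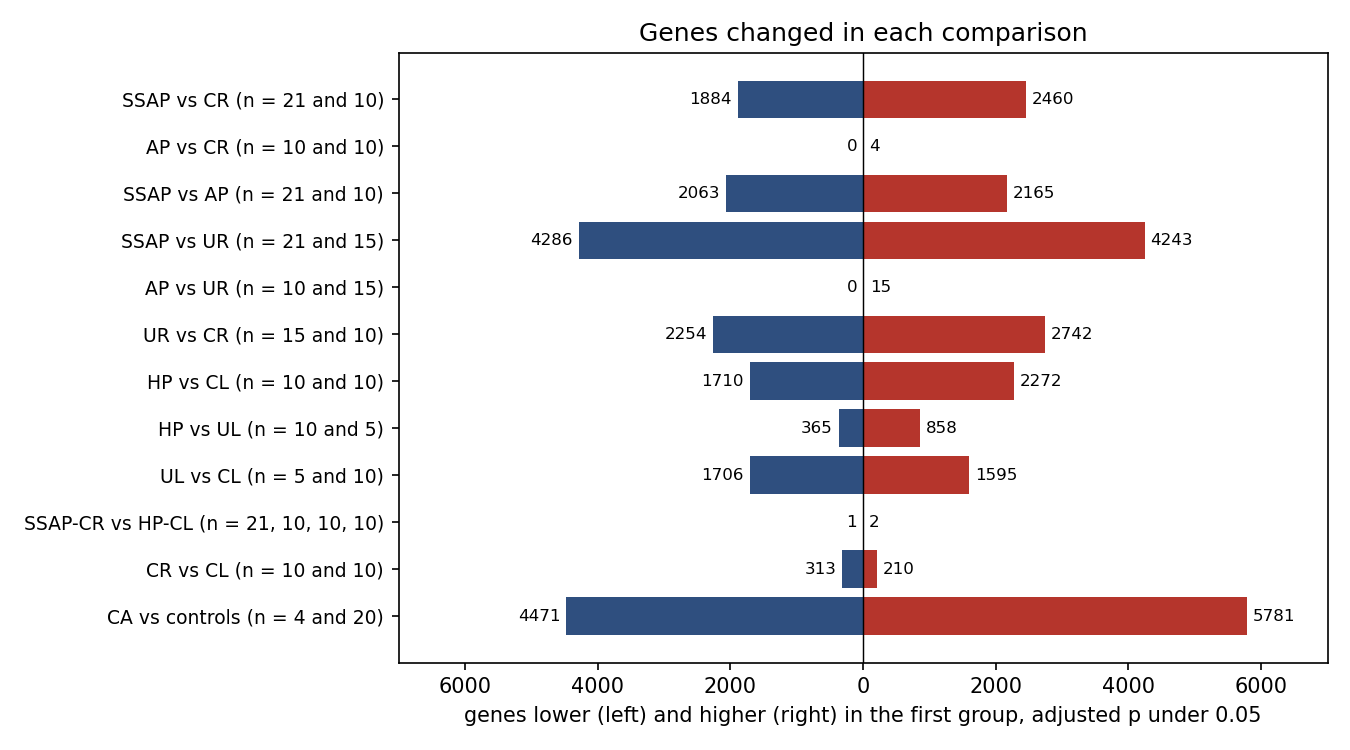
Number of genes called lower (bars to the left) or higher (bars to the right) in the first group of each comparison, at an adjusted p under 0.05 in the edgeR quasi-likelihood test, with the number of libraries of each group. SSAP vs CR called 4344 genes and HP vs CL 3982, against 4 in AP vs CR.

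Sessile serrated polyps expressed a gastric surface and gland programme that was low in control right colon. MUC5AC (a gel-forming mucin of the stomach surface), ANXA10 (a member of the annexin family) and VSIG1 (an adhesion protein of gastric epithelium) were among the 10 genes with the highest fold change. The water channel AQP5 and the secreted proteases KLK7 and KLK10 were among them too. Fetal-like genes such as ANXA1 rose as a list. Genes of ERK signalling output (14 of 17, such as DUSP4) and of epithelial defence (16 of 20, such as REG4) rose too. Their lists passed camera only with the preset correlation. The genes with the lowest fold change included REG1A, a secreted protein of the regenerating family, and several transporters.

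Of 18785 genes tested between SSAP and CR, 4344 changed, 2460 of them higher and 1884 lower, and 1023 changed at least 2-fold (754 higher, 269 lower). The deposited column names start with a number under 20 in 13 of 21 SSAP libraries and in 0 of 10 CR libraries. A batch marked by low numbers was not tested apart from the difference between SSAP and CR. MUC5AC (ENSG00000215182, chromosome 11, 1151580 to 1222364, hg19) averaged 575 ± 543 CPM (SD, n = 21) in SSAP against 2.07 ± 3.12 (n = 10) in CR, a log2 fold change of 8.09 ± 0.84 (SE, edgeR adjusted p = 2.77e-10). In 19 SSAP libraries it lay above every CR library. AQP5 averaged 18.0 ± 11.1 CPM (n = 21) against 0.0378 ± 0.0709 (n = 10; log2 fold change 8.54 ± 0.68, edgeR adjusted p = 9.96e-14). ANXA10 (8.51 ± 0.82), KLK7 (8.41 ± 1.15), KLK10 (8.09 ± 0.76), PSCA (8.08 ± 1.11), TM4SF4 (8.01 ± 0.76), VSIG1 (7.64 ± 0.66) and the connexin GJB5 (7.38 ± 0.83) followed. KLK10 was above every CR library in all 21 SSAP libraries. STYXL2, a pseudophosphatase (7.26 ± 1.09), was above every CR library in 14.

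Among the lower genes, the transcription factor GATA5 had a log2 fold change of -3.88 ± 0.84 (edgeR adjusted p = 0.000431) and REG1A of -3.62 ± 0.92 (edgeR adjusted p = 0.00269; 9.49 ± 16.8 CPM, n = 21, against 117 ± 53.2, n = 10). REG1A reads may include its paralog REG1B, which it closely resembles. SLC4A10, a bicarbonate transporter (-2.17 ± 0.35, edgeR adjusted p = 4.41e-06), SLC30A10, a manganese exporter (-2.07 ± 0.42, edgeR adjusted p = 0.000171), SLC37A2 (-2.10 ± 0.77), the dopamine receptor DRD5 (-2.10 ± 0.75) and the steroid dehydrogenase HSD3B2 (-2.08 ± 0.58) fell as well. The rule for naming genes also picked the detoxification genes CYP1A1 (-3.07 ± 0.90) and CYP1B1 (-2.25 ± 0.55) and the mitochondrial pseudogene MTND2P28 (-2.49 ± 0.90). For CYP1A1, 1 CR library held 99.3% of the CR total, and without it CYP1A1 was higher in SSAP (log2 fold change 3.80, edgeR adjusted p = 0.0103). That library held 88.4% of the CR total for CYP1B1, whose direction also turned without it and with DESeq2. For MTND2P28 1 library held 53.6%, and its reads may come from mitochondrial transcripts.

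By gene list, 11 of 12 gastric-type genes rose in SSAP and none fell (11 rose when p was adjusted over the list alone). The exception was CAPN9, a calpain (0.09, edgeR adjusted p = 0.81). Besides the genes above, CTSE, a protease of gastric epithelium, reached 747 ± 473 CPM (n = 21) against 16.1 ± 5.01 (n = 10; log2 fold change 5.53, edgeR adjusted p = 9.96e-14). Fetal-like and YAP-associated genes rose in 8 of 13 (9 over the list alone), among them ANXA1 (2.44), S100P (4.53), MSLN (3.74) and KRT7 (5.22). These were the 2 lists that passed the camera test with the correlation between genes estimated from the data, with adjusted p = 0.00447 for gastric-type and 0.00982 for fetal-like genes. ERK pathway output genes rose in 14 of 17 (15 over the list alone; camera adjusted p = 0.0865, and 2.48e-11 with the preset correlation). DUSP4, a phosphatase that acts on ERK (4.67), EPHA2 (2.23) and PHLDA1 (2.33) were in front.

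Epithelial defence and inflammation genes rose in 16 of 20 and fell in 1 (16 and 2 over the list alone). Their camera adjusted p was 0.125, and 1.43e-09 with the preset correlation. REG4, a secreted lectin, was the most abundant of those named, at 5489 ± 3342 CPM (n = 21) against 179 ± 104 (n = 10; log2 fold change 4.94, edgeR adjusted p = 5.4e-09). The antiprotease PI3 (4.08), LCN2 (3.69) and CXCL3 (2.46) rose with it. Handling stress genes moved the same way, with 3 of 9 higher and 7 over the list alone (camera adjusted p = 0.472, and 0.00915 with the preset correlation). Interferon response genes rose in 14 of 18, also over the list alone (camera adjusted p = 0.467), such as CXCL11 (4.15), ISG15 (1.54) and IFI6 (1.49). Tight junction genes rose in 7 of 17 (7, with 1 lower, over the list alone; camera adjusted p = 0.221), among them the claudins CLDN1 (3.19), CLDN12 (1.31) and CLDN2 (4.07). Goblet cell genes parted: MUC2, the main intestinal mucin, rose to 8072 ± 4629 CPM (n = 21) from 1751 ± 599 (n = 10; log2 fold change 2.20, edgeR adjusted p = 1.36e-06). AGR2 (1.32) rose with it, whereas ITLN1 (-1.53) and CLCA1 (-1.29) fell. In total, 4 of 12 goblet genes rose and 3 fell (camera adjusted p = 0.95).

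Mitochondrial and ketogenic genes fell in 7 of 13 and rose in none (camera adjusted p = 0.316), with CPT1A (-0.76), PPARGC1A (-1.20) and HADH (-0.72) as examples. The share of counts from the mitochondrial chromosome was lower too, at 3.11 ± 0.906% (n = 21) against 4.09 ± 0.620% (n = 10), and library quality was not told apart from biology here. Proliferation genes fell in 7 of 21 (8 over the list alone; camera adjusted p = 0.559), such as CCNA2 (-0.54) and TOP2A (-0.58). Of 18 absorptive colonocyte genes 4 fell and 1 rose (5 and 1 over the list alone; camera adjusted p = 0.591), among them CA2 (-1.04) and CEACAM7 (-1.13). Bile acid, steroid and xenobiotic genes split into 3 higher and 7 lower of 19 (3 and 9 over the list alone; camera adjusted p = 0.603): the oxidases CYP3A4 (4.03) and CYP3A5 (1.67) rose and the bile acid receptor NR1H4 (-1.55) fell. Of 17 Wnt target and crypt base genes 2 rose and 1 fell (camera adjusted p = 0.847). Of 9 CIMP panel and mismatch repair genes CDKN2A rose (1.14) and MSH6 fell (-0.35; list camera adjusted p = 0.95). None of 10 MHC class II genes passed (camera adjusted p = 0.95). Regional colon genes rose in 5 of 11 and fell in 2 (6 and 4 over the list alone; camera adjusted p = 0.797). HOXB13 (5.15), PRAC2 (4.94) and PRAC1 (4.11) led them, and these were higher in left than in right control colon.

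**Figure D2:**
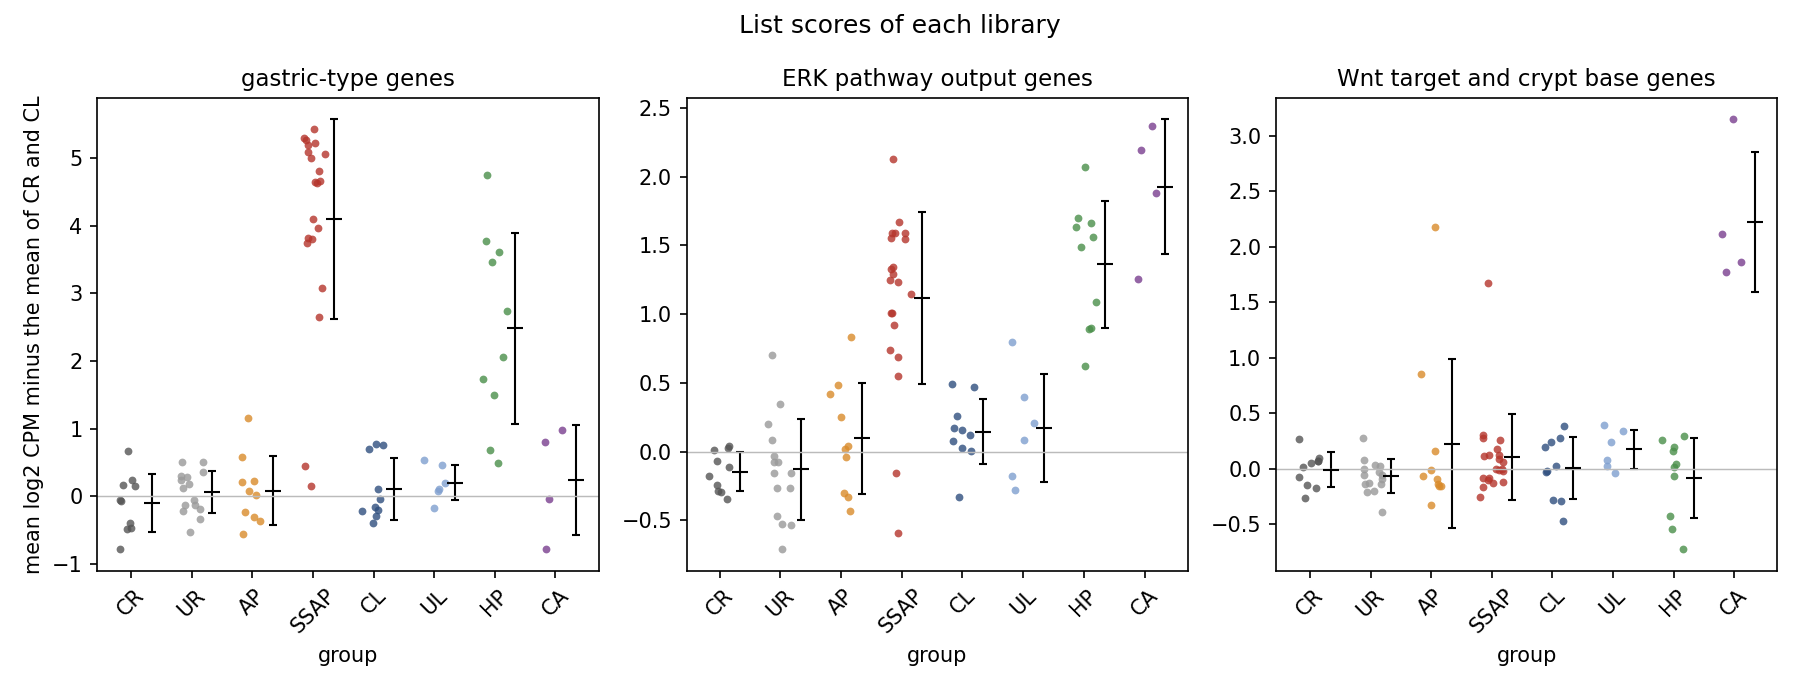
Score of each library (points) for gastric-type, ERK pathway output, and Wnt target and crypt base genes, by group, from the fit of all libraries. The score is the mean log2 CPM of the list minus the mean of CR and CL, and bars show the group mean ± SD. Gastric-type scores of SSAP lie above those of AP, UR and CR in most libraries: in the right colon fit, 19 of 21 SSAP libraries and 1 of 10 AP libraries were above every CR and UR library.

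Against adenomatous polyps, sessile serrated polyps were higher in mRNA of gastric-type and fetal-like genes. AQP5, ANXA10, MUC5AC and TM4SF4 led the higher genes. REG1B, REG1A and REG3A, secreted proteins of the REG family, and the Paneth cell defensin DEFA6 led the lower ones. Of 18785 genes, 4228 changed (2165 higher, 2063 lower in SSAP), 825 of them at least 2-fold. Here too, starting numbers under 20 were found in SSAP only (13 of 21 libraries, against 0 of 10 in AP). A batch marked by them was not tested apart from the polyp type. The log2 fold change was 8.86 ± 0.70 for AQP5, 8.65 ± 0.82 for ANXA10, 8.56 ± 0.86 for MUC5AC and 7.86 ± 0.74 for TM4SF4 (edgeR adjusted p = 1.76e-10 or less). It was -6.46 for REG1A (9.49 ± 16.8 CPM, n = 21, against 836 ± 1326, n = 10; edgeR adjusted p = 3.69e-06), -8.96 ± 1.19 for REG1B and -3.70 ± 0.81 for DEFA6. REG3A (-6.35 ± 0.96) owed 88.6% of its AP total to 1 library and REG1B 80.0%. Reads of REG1A and REG1B, and of DEFA5 and DEFA6, may be shared.

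Gastric-type genes rose in 11 of 12 over AP (camera adjusted p = 0.00422) and fetal-like genes in 7 of 13 (7, with 1 lower, over the list alone; camera adjusted p = 0.0352), with CTSE (4.98) and ANXA1 (2.29) as examples. ERK output genes rose in 13 of 17 and fell in 1 (14 and 1 over the list alone; camera adjusted p = 0.229), led by DUSP4 (4.22). Epithelial defence genes went both ways, 10 of 20 higher and 3 lower (14 and 4 over the list alone; camera adjusted p = 0.585): REG4 (4.57) and PI3 (2.85) were higher in SSAP and the REG genes above were lower. Interferon response genes rose in 7 of 18 (9 over the list alone; camera adjusted p = 0.589) and tight junction genes in 5 of 17 (camera adjusted p = 0.193). Paneth cell markers fell in 3 of 4 (camera adjusted p = 0.585), with DEFA5 at -3.17. Among goblet cell genes 2 of 12 rose, MUC2 by 2.98 (edgeR adjusted p = 1.05e-08), and 5 fell (camera adjusted p = 0.867). Absorptive colonocyte genes fell in 5 of 18 and rose in 1 (7 and 1 over the list alone; camera adjusted p = 0.867), such as MS4A12 (-1.62).

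Against uninvolved right colon, the serrated polyps were higher in mRNA of gastric-type genes and of the proteases KLK7 and KLK10, and lower in that of REG genes and the defensin DEFA6. MUC5AC (8.69 ± 0.71), AQP5 (8.49 ± 0.56), KLK7 (8.23 ± 0.92) and KLK10 (7.98 ± 0.62) led the higher genes (edgeR adjusted p = 6.59e-10 or less). REG1B (-7.07 ± 1.14), REG1A (-5.55 ± 0.94), DEFA6 (-3.46 ± 0.76) and REG3A (-3.24 ± 0.85) led the lower ones (edgeR adjusted p = 0.00184 or less), and 1 UR library held 85.1% of the REG1B and 68.4% of the REG1A total. In all 8529 genes changed (4243 higher, 4286 lower), and 1264 did so at least 2-fold. Without the 5 UR libraries whose deposited column names start with a number under 20, 4611 genes changed. With only libraries of 20 or over (8 SSAP, 10 UR) 608 did. With only libraries under 20 (13 SSAP, 5 UR) 8199 did, so the count depends on which libraries are compared.

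By list, 11 of 12 gastric-type genes rose over UR (camera adjusted p = 0.028, and 0.0517 with libraries of the same starting number summed), with CTSE at 5.60. ERK output genes rose in 15 of 17 (camera adjusted p = 0.173), with DUSP4 at 4.63. Epithelial defence genes rose in 15 of 20 and fell in 4 (camera adjusted p = 0.413), and DUOXA2, a maturation factor of the oxidase DUOX2, rose by 5.75. Fetal-like genes rose in 7 of 13 (camera adjusted p = 0.134). Paneth cell markers fell in 4 of 4 (camera adjusted p = 0.573), glia and neuron markers in 5 of 5 (camera adjusted p = 0.322; S100B -0.95). Enteroendocrine markers fell in 4 of 6 (camera adjusted p = 0.573) and plasma cell markers in 4 of 5 (camera adjusted p = 0.573). Absorptive colonocyte genes fell in 10 of 18 and rose in 1 (11 and 1 over the list alone; camera adjusted p = 0.586; FABP1 -1.05). Mitochondrial genes fell in 11 of 13 (camera adjusted p = 0.413; HADH -0.85) and proliferation genes in 11 of 21 (camera adjusted p = 0.748; PCNA -0.63). MUC2 rose by 2.76 while 6 of 12 goblet cell genes fell and 2 rose (camera adjusted p = 0.749).

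Between adenomatous polyps and control right colon 4 genes passed, all higher in AP, and 13 of 100 splits of the same libraries called as many. They encode MMP7 (a matrix protease, ENSG00000137673, chromosome 11, 102391239 to 102401484, hg19), the pore-forming claudin CLDN2, the prohormone convertase PCSK1 and the glutathione peroxidase GPX2. GPX2 was the most evenly raised, at 327 ± 176 CPM (n = 10) against 147 ± 37.9 (n = 10; log2 fold change 1.15 ± 0.22, edgeR adjusted p = 0.0222), with 7 AP libraries above every CR library. MMP7 (5.78 ± 1.10, edgeR adjusted p = 0.0222) was above every CR library in 3 AP libraries. For CLDN2 (4.17 ± 0.85, edgeR adjusted p = 0.0436) and PCSK1 (3.83 ± 0.77, edgeR adjusted p = 0.0436), 1 library held 72.4% and 91.0% of the AP total. The edgeR test found 2620 genes at an unadjusted p under 0.05, where 939 would be expected. DESeq2 called 109 genes (82 higher, 27 lower), and limma-voom with the starting number as a random block called 0 (2888 at an unadjusted p under 0.05). The edgeR count was also 0 without the CR library with the highest CYP1A1 (2245 at an unadjusted p under 0.05), with only these groups in the fit (3021) and with libraries of the same starting number summed (1678). No list passed camera in AP vs CR. Epithelial defence genes had 0 of 20 past the adjusted p of all genes and 12 higher over the list alone. Their camera adjusted p was 0.754, and 3.7e-06 with the preset correlation. Handling stress genes moved the same way, with 0 of 9 and 6 higher over the list alone (camera adjusted p = 0.754, and 0.004 with the preset correlation). B cell markers had 0 of 6 and 2 lower over the list alone (camera adjusted p = 0.754, and 0.0109 with the preset correlation). Wnt target genes had 0 of 17 and 6 over the list alone (camera adjusted p = 0.754), and gastric-type genes 0 of 12 and 1 over the list alone (camera adjusted p = 0.895). Examples short of the threshold were REG1B (5.37, edgeR adjusted p = 0.0701), the Wnt target SP5 (2.11, edgeR adjusted p = 0.0701) and PSCA (4.48, edgeR adjusted p = 0.0895).

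Against uninvolved right colon, 15 genes passed upward in adenomatous polyps and none downward (edgeR, 3915 genes at an unadjusted p under 0.05). DESeq2 called 49 higher and 21 lower, and 8 of 100 splits of the same libraries called as many genes as the real one. MMP7 (5.56 ± 0.90, edgeR adjusted p = 0.00076), PCSK1 (4.16 ± 0.67, edgeR adjusted p = 0.00076), the vitamin B12 binder TCN1 (4.86 ± 0.90, edgeR adjusted p = 0.00442) and HOXB13 (4.77 ± 0.80, edgeR adjusted p = 0.00121; 9.87 ± 18.3 CPM, n = 10, against 0.362 ± 0.140, n = 15) had the highest fold changes. TCN1 owed 90.2% of its AP total to 1 library, PCSK1 91.0%, HOXB13 54.8% and MMP7 54.3%. Wnt target and crypt base genes rose in 2 of 17, SP5 (2.11) and NKD1 (3.18), and in 7 over the list alone (camera adjusted p = 0.923), while AXIN2 (1.41, edgeR adjusted p = 0.0607) did not pass. Regional colon genes rose in 2 of 11 (3 over the list alone), HOXB13 and PRAC2 (4.41), although camera gave a downward sign and adjusted p = 0.923. No gene passed with only these 2 groups in the edgeR fit (3372 at an unadjusted p under 0.05), nor without the 5 UR libraries of low starting number (846). Of the AP and UR libraries that share a starting number, 9 of 10 pairs correlated over 0.1 (median 0.45), and with that number as a block in the fit of these 2 groups no gene passed (edgeR, 472 at an unadjusted p under 0.05).

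Uninvolved right colon differed from control right colon in many genes by small amounts. Short genes were raised and long genes lowered, and the genes with the highest fold change included the secreted REG1B, the metal-binding MT1M and the protease inhibitor WFDC2. Of 4996 genes changed (2742 higher, 2254 lower), 329 changed at least 2-fold. The log2 fold change was 3.49 ± 1.15 for REG1B (edgeR adjusted p = 0.0243; 85.1% of the UR total in 1 library). It was 2.31 ± 0.79 for the mucosal scavenger receptor DMBT1 (edgeR adjusted p = 0.0278; 250 ± 413 CPM, n = 15, against 50.3 ± 43.1, n = 10). It was 1.83 ± 0.70 for MT1M (edgeR adjusted p = 0.0446, near the threshold) and 1.71 ± 0.53 for WFDC2 (edgeR adjusted p = 0.0178). The DMBT1 medians were 38.1 and 39.6 CPM, with 4 UR libraries above every CR library, and its call held in 8 of 11 other settings (log2 fold change 0.97 with the title number as a block, edgeR adjusted p = 0.447). The lowest were CYP1A1 (-7.59 ± 1.36) and CYP1B1 (-3.13 ± 0.63), which rest mostly on 1 CR library as above, MTND2P28 (-5.64 ± 1.14; 53.6% of the CR total in 1 library) and the zinc finger gene ZKSCAN8 (-1.66 ± 0.49, edgeR adjusted p = 0.015). No list passed camera (adjusted p = 0.981 for each list given here). MHC class II genes rose in 3 of 10 (4 over the list alone; HLA-DMA 0.58), epithelial defence genes in 4 of 20 (3 over the list alone), interferon response genes in 3 of 18 (IFI27 0.97, ISG15 1.08). T cell markers rose in 2 of 6 (CD3D 0.97) and stress genes in 3 of 9 (9 over the list alone; JUNB 0.76). Mast cell markers fell in 2 of 5 (KIT -0.87). Genes called higher had a median length of 2181 bases and those called lower of 6619, against 3713.5 for all tested genes. The correlation of fold change with length was -0.42 (Spearman). With each library's trend on length removed 2754 genes were called. Without the 5 UR libraries of low starting number 0 were (edgeR, 3750 at an unadjusted p under 0.05; DESeq2 called 5485 with all libraries).

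**Figure D3:**
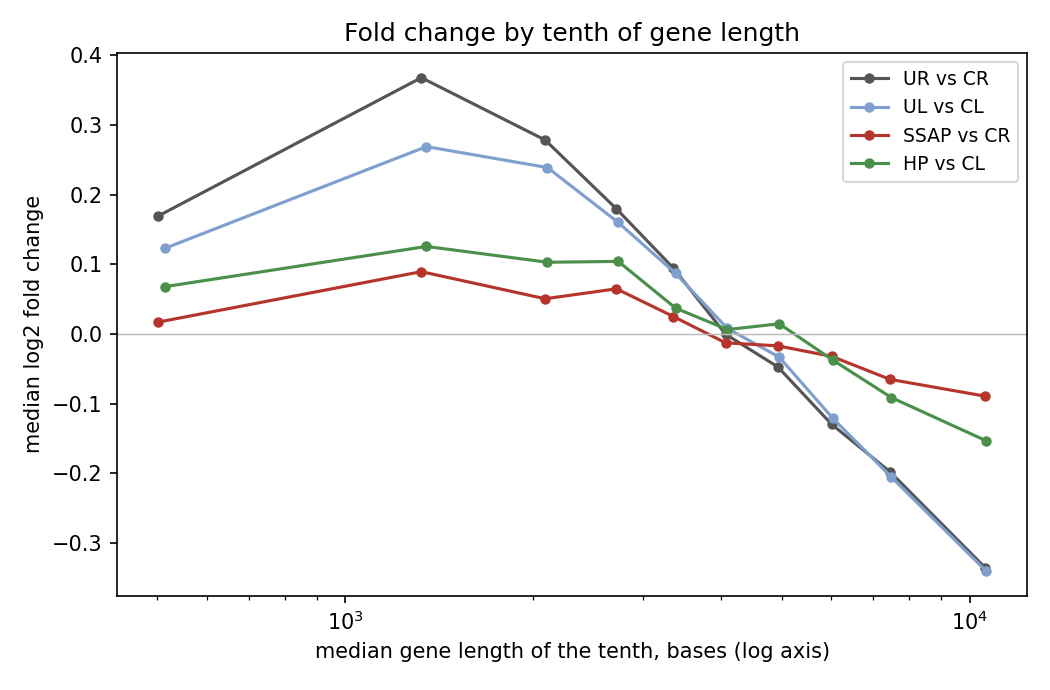
Median log2 fold change of genes in 10 bins of gene length with equal numbers of genes (points, at the median length in bases, log axis) for 4 comparisons with controls. In UR vs CR the median went from 0.37 in bin 2 to -0.34 in bin 10, which holds the longest genes, and in SSAP vs CR from 0.09 to -0.09.

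Hyperplastic polyps of the left colon were higher than control left colon in 9 of 11 gastric-type genes. The list of these passed camera only with the preset correlation. MUC5AC, KLK10, AQP5, VSIG1 and ANXA10 were again among the 10 genes with the highest fold change, joined by the serotonin receptor HTR1D, the cadherins CDH3 and DSG3 and the oxidase factor DUOXA2. The lower genes included the peptidase ENPEP, the serotonin receptor HTR4, the activin receptor ACVR1C and the growth factor BMP3. Of 18486 genes tested, 3982 changed (2272 higher, 1710 lower), 766 of them at least 2-fold. MUC5AC averaged 202 ± 333 CPM (n = 10) against 2.20 ± 3.51 (n = 10; log2 fold change 6.53 ± 1.05, edgeR adjusted p = 0.000236), with 9 HP libraries above every CL library. CDH3 averaged 37.2 ± 33.1 CPM (n = 10) against 0.745 ± 0.667 (n = 10; 5.63 ± 0.70, edgeR adjusted p = 3.27e-05). AQP5 (8.24 ± 1.47), KLK10 (6.78 ± 1.08), VSIG1 (6.28 ± 1.04), HTR1D (5.69 ± 0.71), GJB5 (5.49 ± 0.97), ANXA10 (5.32 ± 1.02), DUOXA2 (5.28 ± 0.94) and DSG3 (4.88 ± 0.71) completed the 10. For HP, 1 library held 71.6% of the total of AQP5 and 73.9% of that of VSIG1. DSG3 was above every CL library in all 10 HP libraries. With limma-voom and the starting number as a random block AQP5 (4.41, adjusted p = 0.0774), KLK10 (4.47, adjusted p = 0.109), ANXA10 (2.87, adjusted p = 0.158) and GJB5 (3.43, adjusted p = 0.0661) lost their call.

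The lowest fold changes in HP vs CL were those of ENPEP (-2.89 ± 0.42, edgeR adjusted p = 6.71e-05), LINC00955 (-2.30 ± 0.79), URAD (-2.28 ± 0.80), HTR4 (-2.12 ± 0.28, edgeR adjusted p = 3.04e-05) and the amino acid transporter SLC38A4 (-2.11 ± 0.75). The chemokine CCL8 (-1.98 ± 0.48), ACVR1C (-1.88 ± 0.33), BMP3 (-1.87 ± 0.64), the glycosyltransferase B4GALNT2 (-1.87 ± 0.64) and CD177 (-1.86 ± 0.58, edgeR adjusted p = 0.0247; 189 ± 234 CPM, n = 10, against 686 ± 385, n = 10) followed. HTR4 and ACVR1C were below every CL library in all 10 HP libraries. Of 9 other settings LINC00955 and URAD kept their call in 6, SLC38A4 and B4GALNT2 in 7 and BMP3 in 8. ERK output genes rose in 14 of 17 (camera adjusted p = 0.0892, and 4.16e-10 with the preset correlation), led by EPHA2 (2.14), DUSP4 (3.82) and ETV4 (2.57). Handling stress genes rose in 4 of 9 (camera adjusted p = 0.777, and 0.0331 with the preset correlation). Gastric-type genes rose in 9 of 11 (9, with 1 lower, over the list alone; camera adjusted p = 0.274, and 1.42e-06 with the preset correlation). Among them were PSCA (4.86), CTSE (3.41), TFF2 (3.87) and TFF1 (3.81), while the gland mucin MUC6 did not pass (0.76, edgeR adjusted p = 0.324). Epithelial defence genes rose in 10 of 15 (11 over the list alone; camera adjusted p = 0.359; REG4 4.65, IL1RN 3.47). Fetal-like genes rose in 8 of 12 (9 over the list alone; camera adjusted p = 0.147; S100P 3.05). With the preset correlation the camera adjusted p was 3.13e-05 for the defence genes and 1.68e-06 for the fetal-like genes. Tight junction genes rose in 5 of 17 (6 over the list alone; camera adjusted p = 0.679; CLDN2 3.18). Mitochondrial genes fell in 6 of 13 (7 over the list alone; camera adjusted p = 0.558), with 3.45 ± 0.848% of counts (n = 10) from the mitochondrial chromosome against 4.11 ± 0.766% (n = 10), and proliferation genes in 6 of 21 (camera adjusted p = 0.777; TOP2A -0.79). Bile acid and xenobiotic genes fell in 4 of 18 (6 over the list alone; camera adjusted p = 0.679; UGT2A3 -1.66) and tuft cell markers in 2 of 5 (4 over the list alone; camera adjusted p = 0.679; BMX -1.44).

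Against uninvolved left colon, hyperplastic polyps were higher in AQP5, DUOXA2, the carboxypeptidase CPB1 and the homeobox gene HOXD12, and lower in CCL8. The log2 fold change was 9.21 ± 2.19 for AQP5 (edgeR adjusted p = 0.0167), 8.24 ± 1.99 for CPB1 (edgeR adjusted p = 0.018; 31.2 ± 37.3 CPM, n = 10, against 0.0930 ± 0.0605, n = 5), 7.31 ± 1.48 for DUOXA2 (edgeR adjusted p = 0.00746) and -2.44 ± 0.54 for CCL8 (edgeR adjusted p = 0.0112). HOXD12 averaged 5.09 ± 3.25 CPM (n = 10) and was listed at 0 in the 5 UL libraries. YBX2 (-2.09 ± 0.55), the tuft cell gene SH2D6 (-1.85 ± 0.54) and the vitamin C transporter SLC23A1 (-1.64 ± 0.40) were lower. In all 1223 genes changed (858 higher, 365 lower), 473 at least 2-fold. The count depends on single libraries: it was 523, 755, 452 or 587 without UL replicate 2, 3, 5 or 6. The starting numbers of the deposited column names gave 5 pairs of an HP and a UL library, though not every UL library had a partner. With that number as a block and only these groups in the fit 29 genes were called (28 higher, 1 lower). With only these groups and no block 140 were (113 and 27). CCL8 was the lower gene left with the block (edgeR adjusted p = 0.046). YBX2, SH2D6 and SLC23A1 lost their call (edgeR adjusted p = 0.253, 0.181 and 0.18), as did CPB1 and DUOXA2 (0.097 and 0.129). No member of the lists below that fell without the block was called lower with it. The rises in these lists are also from the fit without the block, and as 28 genes in all were called higher with it, they need not hold there. ERK output genes rose in 8 of 17 (15 over the list alone; camera adjusted p = 0.0596; EPHA2 1.86, DUSP4 3.37) and gastric-type genes in 7 of 11 (8 over the list alone; camera adjusted p = 0.304; CTSE 3.71, TFF1 4.30). Epithelial defence genes rose in 6 of 15 (7 over the list alone; camera adjusted p = 0.304; IL1RN 3.83) and fetal-like genes in 5 of 12 (6 over the list alone; camera adjusted p = 0.304). Tight junction genes rose in 5 of 17 (6 over the list alone; camera adjusted p = 0.365). Proliferation genes fell in 4 of 21 (7 over the list alone; camera adjusted p = 0.655; PCNA -0.72) and tuft cell markers fell in 2 of 5 (4 over the list alone; camera adjusted p = 0.338).

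Uninvolved left colon resembled uninvolved right colon in its difference from control: many genes changed by small amounts, short genes upward and long genes downward. Complement factor CFD and the complement gene C1QA were among the higher genes. Of 3301 genes changed (1595 higher, 1706 lower), 321 changed at least 2-fold. CFD averaged 64.5 ± 16.2 CPM (n = 5) against 27.6 ± 8.41 (n = 10; log2 fold change 1.22 ± 0.29, edgeR adjusted p = 0.0104), with all 5 UL libraries above every CL library. IL1B (1.93 ± 0.62, edgeR adjusted p = 0.0359), MTND5P11 (1.48 ± 0.47) and CCL2 (1.25 ± 0.43) owed 72.6%, 74.1% and 56.2% of their UL totals to 1 library. The lower genes ANKRD36BP1 (-2.34 ± 0.59, edgeR adjusted p = 0.0128), ZBED6 (-2.99 ± 0.82) and MUC5B-AS1 (-2.37 ± 0.63) overlap or resemble other genes, so their reads may belong to those. DEFA5 (-7.42 ± 2.52) rested on 1 CL library with 98.2% of the CL total. No list passed camera (adjusted p = 0.975 for each list given here). MHC class II genes rose in 3 of 10 (HLA-DMA 0.56, CD74 0.67), macrophage markers in 2 of 6 (C1QA 0.90, C1QB 0.63) and stress genes in 2 of 9 (HSPA1A 0.90). Tight junction genes fell in 2 of 17 (0 over the list alone; OCLN -0.81, TJP1 -0.59). Removing each library's trend on gene length left 1908 genes called, and leaving out UL replicate 2, 5 or 6 left 961, 1010 or 1446.

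The changes of sessile serrated and hyperplastic polyps, each against its own side of the colon, were largely shared. Over 18242 genes tested on both sides the log2 fold changes correlated with r = 0.78 (Pearson). Of these, 1415 genes were higher in both polyp types where 291 would be expected, 821 were lower in both where 171 would be expected, and 6 went in opposite directions. With controls that share no replicate number the correlation was 0.71 and 0.67. The fold changes of UR vs CR and of UL vs CL, which hold no polyps, correlated with r = 0.75 over 18242 genes. With controls that share no replicate number that correlation was 0.59 and 0.61. A difference from the controls that is not due to the polyps may therefore add to the overlap of the polyp types, and it was not removed here. The difference between the 2 polyp effects was tested directly in 19832 genes, and 3 passed (2 higher, 1 lower). Of 100 splits of the libraries 8 called as many. These splits exchanged SSAP with HP and CR with CL, and the 2 sides differ by themselves. They therefore do not test the difference of the effects, and chance is not excluded for these 3. The count was 26 with the title number as a block, 26 without 2 SSAP libraries, 29 in DESeq2 and 0 at an adjusted p under 0.01 (edgeR, 947 at an unadjusted p under 0.05). CYP3A4, a drug- and steroid-metabolizing oxidase (ENSG00000160868, chromosome 7, 99354604 to 99381888, hg19), rose in SSAP (4.03) and did not pass in HP (-0.92), a difference of 4.95 ± 0.99 (edgeR adjusted p = 0.0306). HOXB13 (ENSG00000159184, chromosome 17, 46802125 to 46806540, hg19) rose in SSAP to 29.9 ± 34.4 CPM (n = 21) from 0.823 ± 0.881 (n = 10). In left colon it was at 187 ± 114 CPM in HP (n = 10) and 134 ± 91.7 in CL (n = 10; difference 4.67 ± 0.96, edgeR adjusted p = 0.0351). SLC20A1, a phosphate transporter, fell in SSAP (-1.23) and did not pass in HP (0.46; difference -1.69 ± 0.32, edgeR adjusted p = 0.0187). The controls of the 2 sides differed in level: mean CPM of SLC20A1 was 575 in CR, 243 in SSAP, 150 in CL and 204 in HP. For CYP3A4 it was 1.82 in CR, 29.2 in SSAP, 29.6 in CL and 15.4 in HP. Gastric-type genes had no member of 13 past the threshold (2 over the list alone), with CTSE (2.13, edgeR adjusted p = 0.151) the nearest. The camera adjusted p of the list was 0.0733, and 1.31e-10 with the preset correlation. As the result depends on that choice, a stronger gastric programme in SSAP than in HP was not shown.

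**Figure D4:**
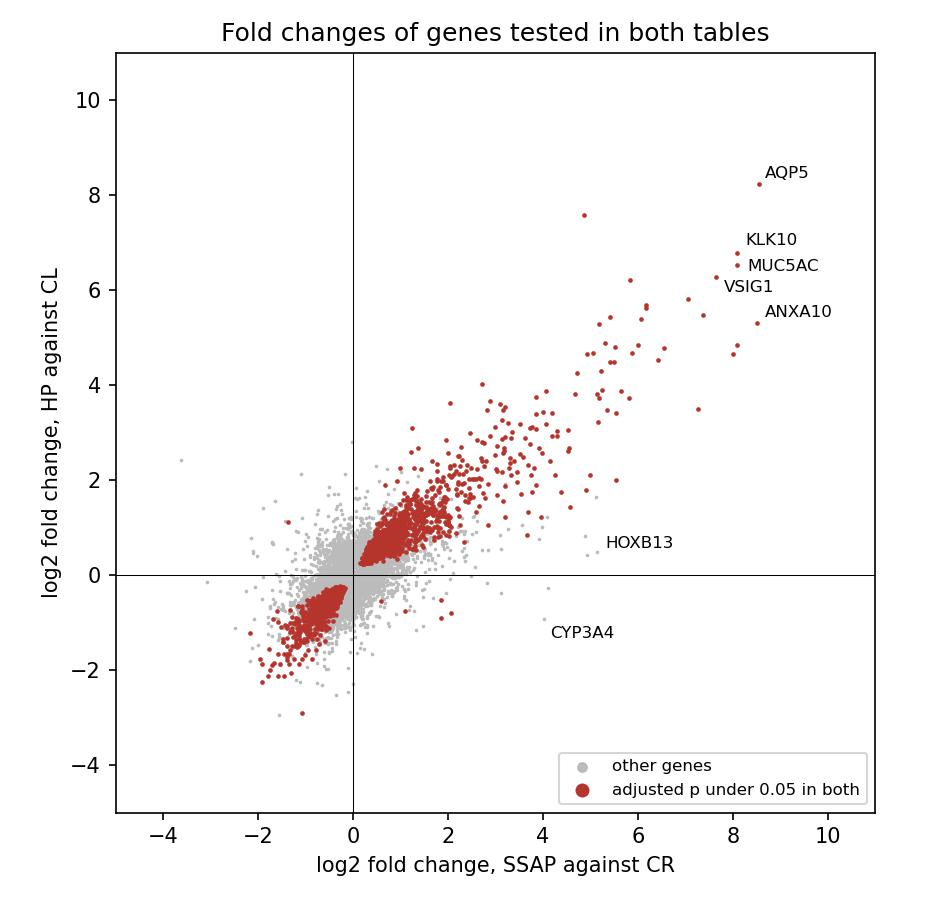
Log2 fold change of each gene tested on both sides (points) in SSAP against CR (horizontal) and HP against CL (vertical), with genes at an adjusted p under 0.05 in both (edgeR quasi-likelihood test) in red. AQP5, KLK10, MUC5AC, VSIG1 and ANXA10 rose in both, and HOXB13 and CYP3A4 rose in SSAP only (log2 fold changes in HP of 0.49 and -0.92).

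Control right and left colon differed in regional identity genes. FAM3B, the urea transporter SLC14A2 and REG1A were higher on the right, and HOXB13, PRAC1, PRAC2 and the hormone INSL5 on the left. FAM3B averaged 77.9 ± 47.9 CPM (n = 10) in CR against 0.698 ± 0.575 (n = 10) in CL (log2 fold change 6.79 ± 1.09, edgeR adjusted p = 2.69e-05). HOXB13 averaged 0.823 ± 0.881 CPM (n = 10) against 134 ± 91.7 (n = 10; -7.31 ± 0.86, edgeR adjusted p = 1.15e-08). SLC14A2 (7.01 ± 1.29), REG1A (5.64 ± 1.38), PRAC2 (-7.13 ± 0.87), PRAC1 (-6.81 ± 1.12) and INSL5 (-5.65 ± 1.10) parted the groups in all 10 libraries. Of 19832 genes 523 changed (210 higher, 313 lower in CR), 292 at least 2-fold. The starting numbers pair the CR and CL libraries. With the number as a block and only these groups in the fit 2932 genes were called (1586 higher, 1346 lower in CR). With only these groups and no block 1492 were (762 and 730), so the balance of directions depends on the fit. Regional colon genes fell in 7 of 11 and rose in 2 (camera adjusted p = 0.00173, and 0.407 with the block and only these groups). Bile acid and xenobiotic genes rose in 4 of 19 and fell in 1 (5 and 3 over the list alone; camera adjusted p = 0.574), with CYP3A4 (-4.03) higher on the left. Enteroendocrine markers fell in 2 of 6 (camera adjusted p = 0.564), the L cell hormones GCG (-2.17) and PYY (-2.25), and 1 of 9 stress genes fell, ATF3 (-2.07; 5 lower over the list alone, camera adjusted p = 0.34).

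Colon cancers differed from the mean of control right and left colon in 10252 of 19832 genes. The labels give no side for the cancers, which lie in a table of their own and have no starting number. A batch was therefore not tested apart from cancer. The CR and CL libraries that pair by number entered as separate libraries. The long non-coding RNA LINC02418, MMP7 and the chemokine CXCL5 led the higher genes, and the proton channel OTOP2 and carbonic anhydrase CA1 the lower ones. Of the genes changed, 5781 were higher and 4471 lower, and 5010 changed at least 2-fold. LINC02418 rose by 9.88 ± 0.59 (edgeR adjusted p = 7.89e-25), MMP7 by 8.56 ± 0.85 (edgeR adjusted p = 4.1e-14; 43.0 ± 39.2 CPM, n = 4, against 0.0898 ± 0.140, n = 10, in CR and 0.115 ± 0.154, n = 10, in CL) and CXCL5 by 8.39 ± 1.08 (edgeR adjusted p = 4.66e-10). LINC00607 (8.62 ± 0.64) owed 98.9% of its CA total to 1 library. Lower were OTOP2 (-8.41 ± 1.43, edgeR adjusted p = 7.37e-07), CA1 (-7.09 ± 1.37, edgeR adjusted p = 1.01e-05) and LINC00955 (-6.27 ± 1.44). MTND2P28 (-6.47 ± 2.45) owed 53.8% of its CR total to 1 library and kept its call in 6 of 13 other settings (log2 fold changes from -6.68 to -0.85).

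In the cancers, Wnt target and crypt base genes rose in 16 of 17 (camera adjusted p = 0.11, and 6.02e-10 with the preset correlation). Among them were MYC (3.67, edgeR adjusted p = 4.5e-28), RNF43 (2.47), SOX9 (2.05) and NKD1 (6.23). Proliferation genes rose in 16 of 21 (18 over the list alone; camera adjusted p = 0.385; AURKA 1.22). Absorptive colonocyte genes fell in 17 of 18 (camera adjusted p = 0.11, and 1.11e-14 with the preset correlation; KRT20 -3.52, CA2 -4.49, SLC26A3 -5.16). Goblet cell genes fell in 8 of 12 (camera adjusted p = 0.133, and 9.6e-05 with the preset correlation). General epithelial markers fell in 5 of 6 (camera adjusted p = 0.133, and 0.00185 with the preset correlation), and handling stress genes rose in 6 of 9 (camera adjusted p = 0.45). Mitochondrial genes fell in 11 of 13 (13 over the list alone; camera adjusted p = 0.133), and 2.08 ± 0.881% of counts (n = 4) came from the mitochondrial chromosome. Bile acid and xenobiotic genes fell in 12 of 19 and rose in 1 (15 and 1 over the list alone; camera adjusted p = 0.133; ABCG2 -6.16), and enteroendocrine markers fell in 6 of 6 (camera adjusted p = 0.156). Epithelial defence genes rose in 17 of 20 (19 over the list alone; camera adjusted p = 0.133; CXCL2 4.79, CXCL1 5.08, CXCL8 6.76). Fibroblast markers rose in 5 of 6 (camera adjusted p = 0.133; COL1A1 3.69) and neutrophil markers in 4 of 4 (camera adjusted p = 0.133). ERK output genes rose in 13 of 17 and fell in 1 (camera adjusted p = 0.156), and fetal-like genes rose in 10 of 13 and fell in 1 (camera adjusted p = 0.133). Interferon response genes rose in 14 of 18 and fell in 1 (camera adjusted p = 0.385), and tight junction genes rose in 3 of 17 and fell in 9 (3 and 10 over the list alone; camera adjusted p = 0.156; CLDN1 5.19). CIMP panel and mismatch repair genes rose in 7 of 11 and fell in 1 (camera adjusted p = 0.133; CDKN2A 2.35, IGF2 2.53). Gastric-type genes did not rise as a list: 5 of 13 rose, AQP5 by 7.81, and 1 fell (2 and 1 over the list alone), with a median of -0.27, a mean of 0.76 and a camera adjusted p of 0.925.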

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

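The tests of the patterns below (UR against CR, AP against CR, and SSAP libraries without gastric-type genes) were chosen after their results were seen, and the splits of libraries before. AP, CR, HP, CL, UL and CA were examined for a single library apart from the rest of its group. The values were library totals, shares of counts on mitochondrial genes and some list scores. SSAP (21 libraries) and UR (15) were not examined in this way. Of 48 such tests 5 found one, where 2.4 would be expected by chance. The total counts of 1 CA library were 56.5 M (next 13.5), those of 1 UL library 63.8 M (next 16.1), and those of 1 CR library 8.36 M (next 12.0). The highest AP score of Wnt target and crypt base genes was 2.20 (next 0.870), and the highest CL score of regional colon genes was 1.71 (next 0.0891). By the edgeR test of the difference itself, CYP3A4 (log2 4.95), HOXB13 (4.67) and SLC20A1 (-1.69) passed between the effects of the 2 polyp types. In 8 of 100 splits as many genes were called, but the splits mixed the 2 sides of the colon and cannot decide. Chance is not excluded for these genes.

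The first pattern is the 4996 genes called between UR and CR. A bias on gene length alone is argued against, since 47.3% of the genes called stayed called with the same sign once each library's trend on length was removed, although the count fell to 2754. A batch of libraries or of collection marked by low starting numbers stays open: leaving out the 5 UR libraries with low numbers left 0 genes called (edgeR, 3750 at an unadjusted p under 0.05), while leaving out 5 others left 6249.5 in the median of 20 draws (1765 to 7231). Between these 5 and the other 10 UR libraries 1 gene was called. The fold change between them correlated with that of UR vs CR (r = 0.66) and with gene length (Spearman -0.31). The 5 libraries are also part of UR vs CR, so part of the first correlation is built in. None of the other groups shares a starting number with CR or CL, so control and uninvolved colon cannot be compared within a number. A difference between colon beside a polyp and colon of the control group, which the design names, stays open and was not tested apart from these.

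The second pattern is the 4 genes called between AP and CR, far fewer than in the other polyps. HP vs CL called 3982 genes with 10 libraries per group, so that number of libraries does not by itself give a low count. The effects and the spread of AP may differ from those of HP, so too few libraries for the AP effects stays open. In AP vs CR 2620 genes had an unadjusted p under 0.05 in edgeR where 939 would be expected, and the self-test recovered 41.8% of 1.5-fold changes. A hidden trend on gene length is argued against by the 5 genes called once it was removed. AP libraries of unlike content may account for the low count, since the Wnt target and crypt base score was above every CR and UR library in 2 of 10 AP libraries, and single libraries held most of the reads of PCSK1 and CLDN2. The labels do not give the share of polyp tissue in a library, so a difference between polyps and a difference in the tissue sampled both stay open.

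The third pattern is 2 of 21 SSAP libraries whose gastric-type score lay within the range of CR and UR (up to 0.905), while the lowest of the other 19 was 3.09. A swap with a CR, UR or AP library is argued against, since 0 of those libraries scored as high as the other SSAP libraries (highest AP 1.44). Tissue beside the polyp, or a single wrong label, cannot be told apart from a serrated polyp without the gastric programme, because 2 and 5 of the 32 list scores of these libraries lay outside the CR and UR range, too few to decide. Without these 2 libraries, 4845 genes were called in SSAP vs CR and 26 in SSAP-CR vs HP-CL.

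Libraries were split at random into groups of the same sizes (100 splits per comparison, the real one included). The splits treat libraries as separate, although libraries that share a starting number correlated (0.32 right, 0.20 left, 0.35 all). In UL vs CL (3301 genes, highest other split 0, 1 split as large) no libraries share a number, and chance can be excluded. The real groups also called the most genes in SSAP vs CR (4344, 670, 1), SSAP vs AP (4228, 52, 1), SSAP vs UR (8529, 562, 1), HP vs CL (3982, 1375, 1), CR vs CL (523, 12, 1) and CA (10252, 7154, 1). There libraries share numbers, so the free splits do not by themselves exclude chance. For CR vs CL it can be excluded, as flips within pairs gave at most 181 genes, fewer than the real 523. In UR vs CR (4996, 5614, 2) no number is shared, but 1 other split called more genes than the real groups. HP vs UL is left open: its free splits (1223, 2283, 4) ignore the pairs, and the 16 flips within pairs are too few for a share under 0.05 (real 1223, highest other 196). Chance cannot be excluded for AP vs CR (4 genes, highest other split 9, 13 splits as large) and AP vs UR (15, 2594, 8). For SSAP-CR vs HP-CL (3, 17, 8) the splits mixed the 2 sides of the colon, which differ. They cannot decide there, and chance is not excluded. The splits with 2594, 2283 and 5614 genes called more than the real groups, and which libraries they separated was not examined.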

How the results depend on the processing

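The removal of the trend on gene length and the settings that leave out libraries by starting number, gastric-type score or CYP1A1 were chosen after seeing the data, as was the fit with all 6 UL libraries. The other settings were planned. DESeq2's Wald test moved AP vs CR from 4 genes to 109, AP vs UR from 15 to 70, HP vs UL from 1223 to 1961 and SSAP-CR vs HP-CL from 3 to 29. At an adjusted p under 0.01 the counts were 0 (AP vs CR, 2620 at an unadjusted p under 0.05 in edgeR), 9 (AP vs UR), 239 (CR vs CL), 1610 (HP vs CL), 171 (HP vs UL), 2319 (SSAP vs AP), 2536 (SSAP vs CR), 5588 (SSAP vs UR), 0 (SSAP-CR vs HP-CL, 947 at an unadjusted p under 0.05), 350 (UL vs CL) and 684 (UR vs CR). With a 2-fold minimum they were 5010 (CA vs controls), 292 (CR vs CL), 766 (HP vs CL), 473 (HP vs UL), 825 (SSAP vs AP), 1023 (SSAP vs CR), 1264 (SSAP vs UR), 321 (UL vs CL) and 329 (UR vs CR).

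With libraries of 1 group and the same starting number summed, AP vs CR called 0 genes (1678 at an unadjusted p under 0.05), AP vs UR 9 and SSAP-CR vs HP-CL 7. limma-voom with the starting number as a random block called 0 in AP vs CR (2888), 0 in AP vs UR (3200), 1500 in CR vs CL and 6 in SSAP-CR vs HP-CL. With only the groups compared in the fit, edgeR called 0 in AP vs CR (3021), 0 in AP vs UR (3372), 1492 in CR vs CL, 140 in HP vs UL and 5 in SSAP-CR vs HP-CL. In AP vs UR, 1 CPM in 50% of the libraries gave 4 genes and no filter beyond 1 count gave 23. Without the UR libraries of low starting number AP vs UR called 0 (846), UR vs CR 0 (3750) and SSAP vs UR 4611. SSAP vs UR called 608 with only libraries of 20 or over and 8199 with only libraries under 20. Without the CR library with the highest CYP1A1, AP vs CR called 0 (2245). Without 2 SSAP libraries SSAP-CR vs HP-CL called 26. With the trend on gene length removed, SSAP-CR vs HP-CL called 5, UL vs CL 1908 and UR vs CR 2754, and with all 6 UL libraries UL vs CL called 2092.

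With the starting number as a block and only the groups compared in the fit, CR vs CL called 2932 genes, HP vs UL 29 and AP vs UR 0 (472 at an unadjusted p under 0.05), against 1492, 140 and 0 with only those groups and no block. SSAP vs UR called 11427 with the block and 7639 with only those groups and no block. With the title number as a block AP vs UR called 0 (2501), SSAP-CR vs HP-CL 26 and UR vs CR 3271. The list of regional colon genes in CR vs CL lost its call with the block and only those groups (camera adjusted p = 0.407), and this setting changed no other list call where numbers pair the libraries. Leaving out 1 library at a time gave 452 to 1445 genes in HP vs UL (523 without UL replicate 2, 755 without 3, 452 without 5 and 587 without 6), 961 to 4270 in UL vs CL (961 without UL replicate 2, 1010 without 5 and 1446 without 6) and 9055 to 9831 in CA vs controls.

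Directions turned in SSAP vs CR for CYP1A1 (3.33 with DESeq2, 1.23 with limma-voom, 3.80 without the CR library with the highest CYP1A1) and CYP1B1 (0.73 with DESeq2, 0.70 without that library), in UL vs CL for MTND5P11 (-0.14 to 1.73 with 1 library left out, the lowest without UL replicate 2) and in UR vs CR for MTND2P28 (0.0178 with DESeq2). Of the values of the 107 named results under all settings, 996 kept direction and call, 154 lost the call and 7 turned. For the 384 list tests, 1121 values stayed on the same side of the threshold, 93 gained a call with the preset correlation and 2 lost it, the second being gastric-type genes in SSAP vs UR with libraries summed (adjusted p = 0.0517).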

Other observations

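Markers of non-epithelial and rare epithelial cells moved in small sets in SSAP vs CR, and no marker list passed camera. Glia and neuron markers fell in 3 of 5 (SOX10 -1.03; camera adjusted p = 0.316), mast cell markers in 3 of 5 (KIT -0.87, CPA3 -0.87; camera adjusted p = 0.643) and enteroendocrine markers in 2 of 6 (NEUROD1 -1.56, CHGB -1.37; camera adjusted p = 0.542). Neutrophil markers rose in 2 of 5 (FCGR3B 2.43, CXCR2 1.09; camera adjusted p = 0.628), epithelial markers in 2 of 6 (KRT19 1.04, KRT18 0.75; camera adjusted p = 0.542), macrophage markers in 1 of 6 (CD68 0.65; camera adjusted p = 0.95), T cell markers in 1 of 6 (CD2 0.61; camera adjusted p = 0.632) and handling stress genes in 3 of 9 (7 over the list alone; camera adjusted p = 0.472). Adipocyte markers fell in 1 of 2 (PLIN1 -0.82; camera adjusted p = 0.542). No member passed among markers of B cells (0 of 6, camera adjusted p = 0.628), plasma cells (0 of 5, 0.591), fibroblasts (0 of 6, 0.847), smooth muscle (0 of 6, 0.961), endothelial cells (0 of 4, 0.95), Paneth cells (0 of 4, 0.739), tuft cells (0 of 5, 0.884) and red blood cells (0 of 3, 0.628).

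Ribosomal protein genes, a group chosen after the data were seen, had higher fitted values in uninvolved than in control colon. In UR vs CR 69 of 77 passed upward and none downward (median log2 fold change 0.76, and 0.61 with the trend on gene length removed), and in UL vs CL 54 did (0.61 and 0.48). Without the 5 UR libraries of low starting number no gene was called in UR vs CR (edgeR, 3750 at an unadjusted p under 0.05), so the UR vs CR calls depend on those libraries. In SSAP vs UR 70 of 77 were lower (-0.49 and -0.42), and in SSAP vs CR 3 were higher (0.24 and 0.20). In AP vs CR no member passed in edgeR (median 0.52). The fold changes of UR vs CR and of UL vs CL correlated over 18242 genes with r = 0.75, with 1221 genes higher in both where 237 would be expected and 1086 lower in both where 208 would be. With controls that share no replicate number r was 0.59 and 0.61, but 1 gene in the first such split and 0 in the second were called the same way on both sides (edgeR). In the first split UR vs CR called 1565 genes higher and 1088 lower and UL vs CL 1 and 1. In the second UR vs CR called 0 and 2 and UL vs CL 173 and 394, so in each split 1 side had almost no genes to share. With all controls and the trend on gene length removed r was 0.71.

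List scores were compared with the range of the CR and UR libraries. The score of regional colon genes, which include HOXB13 and PRAC2, was above that range in 15 of 21 SSAP libraries. Tight junction scores were above that range in 19 of 21 SSAP libraries and ERK output scores in 17 of 21, and mitochondrial scores were below it in 13 of 21. In AP the fetal-like score was above the range in 4 of 10 libraries and the ERK output score in 1 of 10.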
